A study of Petunia x hybrida with 10 samples.

How the data were processed

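The material was corolla (the petals of the flower) of petunia cultivar Mitchell, a laboratory line, after 16 h in air or 16 h with the gaseous plant hormone ethylene at 2 µl/l, per the labels. RNA was fragmented and immunoprecipitated with an antibody against a modified adenosine, and the bound RNA was sequenced, per the labels' protocols. An input library without immunoprecipitation is named in the same protocols and was not analysed here. Libraries were grouped by their titles into N1-methyladenosine (m1A) from air (n = 3) and ethylene (n = 3), and N6-methyladenosine (m6A) from air (n = 2) and ethylene (n = 2). No label says that the libraries of a group came from separate plants, so p-values of the exact permutation tests over libraries measure only the spread between these samples, which may be technical. The p-values from shuffles, placements and binomial tests are computed over regions of these libraries and measure no spread between plants.

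The labels hold 2 conflicts that bear on the values. The protocol text of the m6A-titled libraries names the same anti-m1A antibody as that of the m1A libraries, so that "m6A" below means the title and not a verified target. The submitters' processing notes name a human and a mouse genome build, whereas the peak lists use scaffold names of the Petunia axillaris v1.6.2 assembly (prefix Peaxi162), and coordinates are given on those scaffolds. The same notes name CASAVA 1.4, cutadapt 1.9.3, STAR 2.5.1b and MACS 1.4.2 without stating what each was used for or how it was set.

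The deposited files are peak lists, 1 per library, with scaffold, start, end, a numbered peak name and a score for each peak. The m1A lists have 5 columns and no strand, and the m6A lists have 6 columns with a strand. The deposited unit is a score per peak, given by the authors' peak caller for that library alone. The files and labels do not say how the score is scaled, so it was used to rank or filter peaks, and no difference in score between lists is reported as a change. A common minimum score across lists (the pooled median of a mark, or 100 for the m6A lists) and the share of peaks at the most common score assume that the scale is the same in each list, which was not established. The most common score was exactly 3100, which limits any ranking near the top. The pooled median of the m1A lists was also 3100, so a minimum there kept 41.0 to 70.9% of an m1A list. In the m6A lists the pooled median was 78.2. The lowest score was 100 in the m1A lists and 13.0 in the m6A lists. Peak numbers skip in every list, so each list is a subset of the numbered peaks, by a filter not given in the sources used here. The files carry no read counts, so depth is unknown for each library, and no interval or detection limit that needs depth is given. A library sequenced more deeply can yield a longer list at the same level of modification, and the length of a list cannot be corrected for this.

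Peaks of the libraries of 1 mark were merged into regions wherever they shared 1 bp or more, and a region was called present in a library that had a peak in it. Regions in 2 or more libraries of a mark are called reproducible. Numbers of peaks per library were compared between treatments with exact two-sided permutation tests, whose smallest possible p was 0.1 for m1A and 0.33 for m6A. Regions found in every library of 1 treatment and in no library of the other were counted and set against 2000 shuffles of the presence table. Each shuffle kept the number of libraries of each region and the number of regions of each library, with 50 sweeps before the first draw. The permutation p was two-sided, its smallest possible value was 0.001, and it was adjusted by the Benjamini-Hochberg method over the 4 such counts. The shuffle treats regions as independent units, which neighbouring regions may not be. Agreement between lists was measured with the Jaccard index, the shared bp over the bp covered by either list, and the mean within treatments was compared with the mean between treatments by exact permutation over the splits of the libraries. Overlap of reproducible m1A and m6A regions was compared with 1000 random placements of the m1A regions, each on its own scaffold up to the last peak end seen in any list, with a smallest possible p of 0.002. A random position can fall outside transcribed sequence, so the chance share from placement may be too low, and moves of 1.5 to 5 kb were added for comparison after the data were seen.

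The regions named below follow a rule set before the data were examined. It takes, for each mark, up to 10 regions with the highest mean score percentile within the lists among those in every library, those in every air and no ethylene library, and those in every ethylene and no air library. Ties were resolved by position, and 73 m1A air-specific regions and 26 m6A regions of all 4 libraries tied at a score of 3100, so that position decided which 8 of each were named. Regions outside this rule are said to be so where they appear. Tests, alternatives and the list of fixed gene groups were also set before the data were examined, apart from alternatives said to have been added.

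The shuffle test was tested on simulated tables drawn with 36717 m1A regions or 3280 m6A regions, 40 simulations each, for regions in every air and no ethylene library. Regions that fell in no library were dropped, so the tested tables were smaller. Regions were drawn independently, with a tendency to recur that was not fitted to the data. The simulations therefore do not cover neighbouring regions that go together, and no planted number below 200 was tried. With nothing planted, 1 of 40 m1A simulations and 3 of 40 m6A simulations passed the threshold of 0.05. With 200 planted air-only regions, 40 of 40 passed for either mark, with a median excess of 120 regions for m1A and 113 for m6A, so the excess over the shuffles understates the number planted.

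Alternatives covered a minimum score at the pooled median of the mark, 50% overlap of the shorter peak, lists of equal length with ties taken at random under a fixed seed, a width of 100 bp or more, covered sequence in place of peak number, a replicate block, leaving out each library in turn, and, added after the data were seen, loci made by chaining peaks with gaps of 2 kb or less. Gene names, positions within transcripts and the fixed gene groups were not analysed here, because no annotation of the scaffolds was used. The computations were done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.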

Results

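The data comprised 10 lists of peaks of immunoprecipitated RNA from petunia corollas kept in air or treated with ethylene, a hormone known to hasten petal senescence. N1-methyladenosine (m1A), an adenosine methylated on the face that pairs with other bases, was profiled in 3 air and 3 ethylene libraries. The companion lists titled N6-methyladenosine (m6A), a common internal mark of messenger RNA, came from 2 air and 2 ethylene libraries. The m1A lists held between 1013 and 17573 peaks on 417 to 1154 scaffolds, with median peak widths of 146 to 162 bp. The m6A lists held between 1451 and 1704 peaks on 625 to 666 scaffolds, with median widths of 261 to 286 bp. Sequencing depth was unknown for each library, and the 2 kinds of list had different lowest scores, so lengths of m1A and m6A lists were not compared with each other.

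The first comparison asked whether ethylene changed the number of m1A peaks detected in corolla mRNA. Fewer m1A peaks were listed on average after ethylene, 5533 ± 3923 (SD, n = 3), than in air, 13309 ± 5757 (SD, n = 3), a ratio of 0.416. The air libraries held 15593, 17573 and 6760 peaks and the ethylene libraries 7526, 1013 and 8059. Peaks covered 2591 ± 1137 kb in air (SD, n = 3) and 1058 ± 790 kb after ethylene (SD, n = 3). The libraries of the treatments overlapped, since the air library with 6760 peaks lay below 2 of the ethylene libraries, and the difference did not pass the test (exact permutation p = 0.3, 20 regroupings, smallest possible 0.1). The ratio was 0.586 without ethylene library 2, which had the shortest list.

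**Figure D1:**
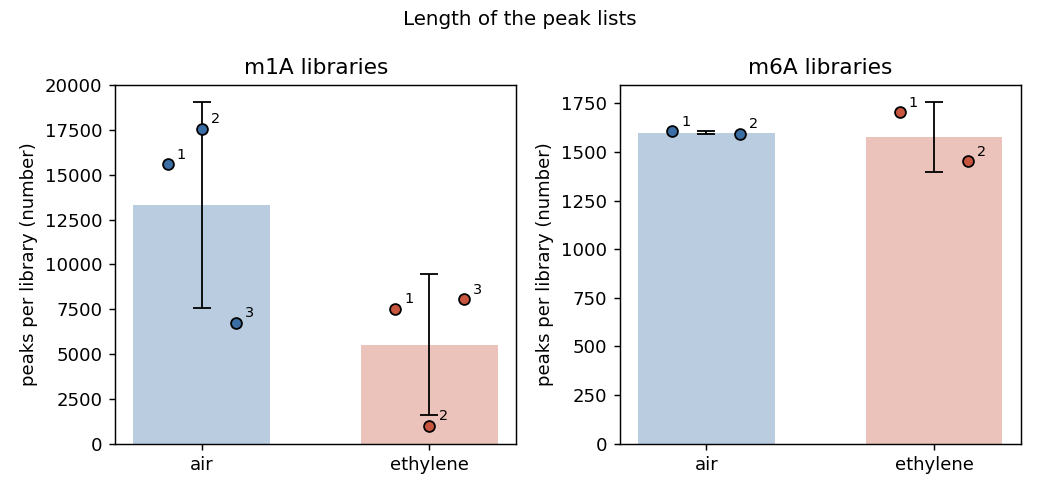
Number of peaks in each library's list, for m1A (left) and m6A (right), with points for single libraries numbered by replicate, bars for group means from 0 and error bars for the SD. In m1A, air library 3 (6760 peaks) lies among the ethylene libraries, whose lowest is 1013, and in m6A the 4 libraries lie between 1451 and 1704.

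The same question was asked of the m6A lists. Mean list lengths of the 2 treatments were close, 1599 ± 8.49 peaks in air (SD, n = 2) and 1578 ± 179 after ethylene (SD, n = 2), a ratio of 0.987. The air libraries held 1605 and 1593 peaks and the ethylene libraries 1704 and 1451. The ethylene libraries lay on either side of both air libraries (exact permutation p = 1, smallest possible 0.33), and the ratio was 1.07 without ethylene library 2. The ethylene to air change in list length was not shown to differ between m1A and m6A, with a difference in the natural log ratio of geometric means (0.321 for m1A and 0.983 for m6A) of -1.12 (exact permutation p = 0.267, 120 regroupings).

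Few m1A regions recurred in every library. Of 36717 merged m1A regions, 24179 (65.9%) were seen in 1 library, 12538 (34.1%) in 2 or more and 60 in all 6. The 10 named among the 60 had a score of 3100 in each of the 6 libraries, and none of the 10 overlapped an m6A region (2 of all 60 did). They included Peaxi162Scf00198 864961 to 867810, the widest of the 10 at 2850 bp, Peaxi162Scf00016 3443634 to 3445034, 1401 bp wide, and Peaxi162Scf00147 504524 to 505547, 1024 bp wide. In air, 1490 regions were present in all 3 libraries, 4.90% of the 30394 seen in any. After ethylene, 147 were present in all 3, 1.03% of 14218. Both this count and the 60 were limited by ethylene library 2, which held 1009 regions, and without it 1815 regions were in both ethylene libraries (13.3% of 13644) and 411 in all 5 m1A libraries. With 1 air library left out, the share present in both others was 12.4 to 20.3%, highest without air library 3 (5565 of 27408).

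Ethylene-specific and air-specific m1A regions were then sought. In all 3 air libraries and no ethylene library, 488 regions were found, and shuffled tables held 489 on average (95% of shuffles 452 to 529, ratio 0.997, permutation p = 0.959, adjusted p = 0.959 over the 4 counts). The count exceeded the shuffles without air library 3 (2960 against 2767, ratio 1.07, permutation p = 0.001) and with loci in place of regions (519 against 477, ratio 1.09, permutation p = 0.0260), an alternative added after the data were seen. The air-specific regions with the highest mean score percentile were Peaxi162Scf00843 206976 to 207202 and Peaxi162Scf00100 786772 to 786953, with scores between 3100 and 3173. Another 73 regions tied behind them, among them Peaxi162Scf00020 337981 to 339254 and Peaxi162Scf00007 385127 to 385898. In all 3 ethylene libraries and no air library, 13 regions were found against 6.90 in shuffled tables (95% of shuffles 2 to 12, ratio 1.89, permutation p = 0.0390), which did not pass the threshold after adjustment over the 4 counts (adjusted p = 0.0780). Among the 10 named of these, Peaxi162Scf00560 437425 to 439977 was 2553 bp wide, Peaxi162Scf00046 726762 to 728677 was 1916 bp wide and Peaxi162Scf00079 1649174 to 1649567 was 394 bp wide. None of the 10 named regions of either treatment overlapped an m6A region. Such overlap was rare among all m1A regions of 3 libraries (139 of 3014), so its absence in 10 says little. Without ethylene library 2, 319 ethylene-specific regions stood against 289 in shuffled tables (ratio 1.10, permutation p = 0.0680). With lists of equal length the count was 4 against 1.16 (ratio 3.45, permutation p = 0.0540). Most peaks kept in the longer lists were then drawn at random from those tied at a score of 3100, so this setting does not rank peaks by strength. The unadjusted threshold was passed with loci (9 against 3.10, ratio 2.91, permutation p = 0.0060) and without air library 3 (19 against 10.03, ratio 1.895, permutation p = 0.0070).

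**Figure D2:**
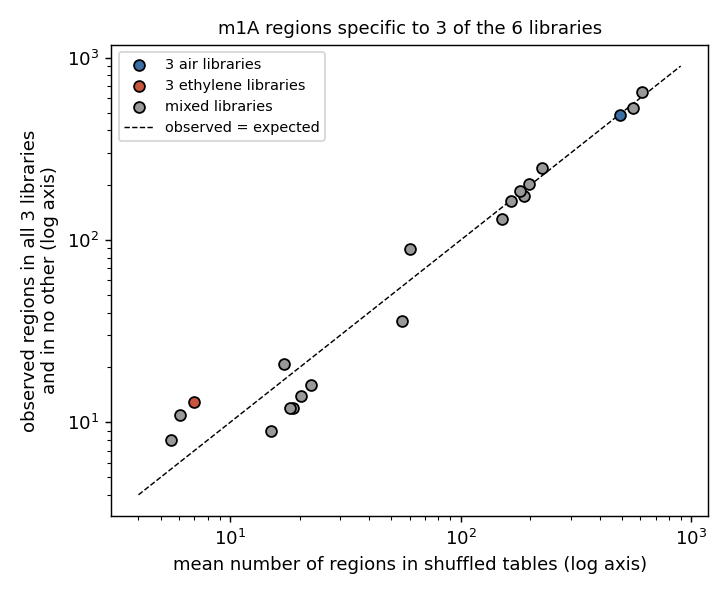
Observed number of m1A regions in all 3 libraries of a set and in no other (vertical, log axis) against the mean in shuffled tables (horizontal, log axis), for each of the 20 sets of 3 of the 6 m1A libraries. The air set (488 against 489) lies on the dashed line of equality, the ethylene set (13 against 6.95 in this set of shuffles) lies above it, and mixed sets lie on both sides.

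A set mixing treatments also departed from the shuffles. Regions in air library 3, ethylene library 1 and ethylene library 3 and in no other numbered 89 against 60.5 (ratio 1.47, permutation p = 0.001, the smallest the shuffles can give). The lists of these libraries were of like length, with 6760, 7526 and 8059 peaks. Regions in air libraries 1 and 2 and ethylene library 2 and in no other numbered 36 against 55.7 (ratio 0.646, permutation p = 0.0050). These were 2 of the 20 sets of 3 libraries, with no adjustment.

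The recurrence of m6A regions was measured over 4 libraries. Of 3280 merged m6A regions, 1567 (47.8%) were in 2 or more libraries and 558 (17.0%) in all 4. In air, 914 regions were in both libraries, 40.02% of the 2284 seen in either, and after ethylene 814 were in both, 34.8% of 2341. Of the 10 named among the 558, Peaxi162Scf00439 816094 to 816380 on the minus strand had the highest mean percentile, followed by Peaxi162Scf01006 247459 to 247938, also on the minus strand. The other 8 were taken by position from 26 that tied. Of the 10, 6 overlapped an m1A region. Peaxi162Scf00025 2862719 to 2863332 (minus) and Peaxi162Scf00027 501313 to 501702 (plus) each overlapped an m1A region seen in 4 m1A libraries.

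More m6A regions were specific to air than shuffled tables held. In both air libraries and neither ethylene library, 138 regions were found against 106 (95% of shuffles 89 to 123, ratio 1.30, permutation p = 0.001, the smallest the shuffles can give, adjusted p = 0.0040). In both ethylene libraries and neither air library, 84 were found against 98.5 (95% of shuffles 83 to 116, ratio 0.853, permutation p = 0.0790, adjusted p = 0.105). The named air-specific regions were led by Peaxi162Scf00016 1892827 to 1892904 (plus, score 3100 in both libraries), Peaxi162Scf00131 1311417 to 1311544 (plus, scores 1485 and 3100) and Peaxi162Scf00197 73048 to 73104 (plus, scores 1033 and 1078). The named ethylene-specific regions were led by Peaxi162Scf00131 1309869 to 1309994 (plus, scores 1955 and 3184), Peaxi162Scf00327 835462 to 835689 (minus, scores 819 and 1247) and Peaxi162Scf00419 276028 to 276885 (plus, scores 604 and 1306). An m1A region overlapped 2 of the 10 named air-specific and 7 of the 10 named ethylene-specific regions, a difference that was not tested. Most specific regions were weak, with a lowest score under 100 in 118 of 138 (85.5%) air-specific and 73 of 84 (86.9%) ethylene-specific regions, against 280 of 558 (50.2%) of those in all 4 libraries.

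The air-specific excess did not pass the threshold among peaks at or above the median score (79 against 67.5, ratio 1.17, permutation p = 0.0840). Leaving out a library leaves 1 library in a treatment, and the ratio was then 0.943 without air library 1 (517 against 548, permutation p = 0.002, a deficit), 0.989 without air library 2, 0.966 without ethylene library 1 and 1.39 without ethylene library 2. Ethylene library 1 stood apart from the other m6A libraries, with 35.6% of its regions seen in no other m6A library (21.02 to 26.3% in the others), 64.5% of its peaks under a score of 100 (50.2 to 54.4%) and the 3 lowest Jaccard indices among m6A pairs (33.8 to 35.4%). A mixed pair, air library 2 with ethylene library 2, also held more regions of its own than the shuffles, 105 against 85.2 (ratio 1.23, permutation p = 0.0190), and air library 2 with ethylene library 1 held fewer, 91 against 121 (ratio 0.755, permutation p = 0.001). The ethylene-specific count lay above the shuffles among peaks at or above the median score (36 against 29.6, ratio 1.22, permutation p = 0.226) and without ethylene library 2 (691 against 612, ratio 1.13, permutation p = 0.001).

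The next comparison asked whether peak lists of 1 treatment resembled each other more than lists of different treatments. Pairs of m1A lists shared little sequence, with a mean Jaccard index of 10.3% over 15 pairs and a range of 1.78 to 20.9%. The index cannot exceed the shorter list's covered bp over the longer's. The m1A lists covered 151 to 3435 kb and the m6A lists 495 to 587 kb, so low m1A indices partly follow unequal lengths. The mean was 15.5% within air (12.6 to 20.9%), 6.60% within ethylene (2.75 to 13.9%) and 9.84% between treatments (1.78 to 15.01%). The low mean within ethylene came from the 2 pairs with ethylene library 2 (2.75 and 3.13%), and the remaining ethylene pair had 13.9%. Within minus between was 1.22 percentage points (exact permutation p = 0.3 over 10 splits, smallest possible 0.1). Its sign was negative by the share of the shorter list's peaks that overlapped the other list, and also without air library 1 or air library 2. Pairs of m6A lists had a mean index of 38.6% over 6 pairs (33.8 to 45.2%), and within minus between was -0.301 points (exact permutation p = 1 over 3 splits). Of the peaks of the shorter list in a pair, 22.7 to 40.8% overlapped the other m1A list, against 1.78 to 5.04% after moves of 1.5 to 5 kb. For m6A pairs these shares were 51.0 to 62.4% and 0.620 to 1.51%.

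**Figure D3:**
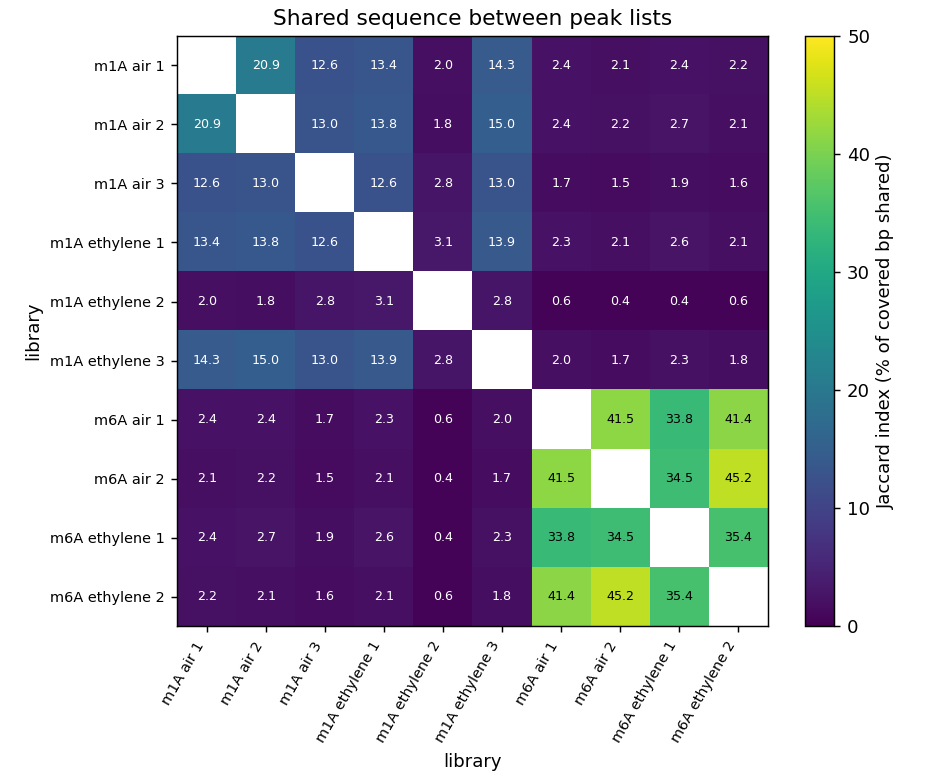
Jaccard index (percent of covered bp that is shared) for each pair of the 10 peak lists, with libraries on both axes and the value printed in each cell. Pairs of m6A lists lie between 33.8 and 45.2%, pairs of m1A lists between 1.78 and 20.9%, and pairs of an m1A with an m6A list between 0.410 and 2.68%.

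The last comparison asked whether m1A and m6A peaks marked the same places. Of 12538 reproducible m1A regions, 313 (2.496%) overlapped 1 of the 1567 reproducible m6A regions, against 0.178% ± 0.0377 (SD over 1000 placements) when placed at random on their scaffolds (placement permutation p = 0.002, the smallest possible). Seen from the other mark, 306 of 1567 m6A regions (19.5%) overlapped a reproducible m1A region, against 1.404% when placed at random and 3.23% when moved by 1.5 to 5 kb. With m1A regions moved by 1.5 to 5 kb, 0.415% overlapped. The overlap was 2.05% for m1A regions of 1 library, 2.33% for those of 2 and 2.79% for 3. For those of 4, 5 and 6 libraries it was 2.68, 3.14 and 1.67%, the last from 1 of 60 regions. Mean region width was 143 bp for 1 library, 555 bp for 5 and 705 bp for 6. Greater width favours overlap, and these shares were not adjusted for it, so no trend with recurrence can be read from them. Only 1 region, Peaxi162Scf00338 184003 to 184496, was present in all 6 m1A and all 4 m6A libraries, with identical bounds in both sets. It lay outside the naming rule and was singled out after its values were seen. Exact edges were common, since 38.1 to 54.6% of overlapping m1A and m6A peaks shared a start and 34.2 to 56.9% an end. The overlap was 1.59% with air libraries alone, 1.67% with ethylene libraries alone and 1.58% with m6A peaks of score 100 or more, each above its random placements (placement permutation p = 0.002). Placed and moved regions can fall outside transcribed sequence. The excess therefore cannot separate marking of the same places from a shared restriction of both marks to transcribed sequence.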

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

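The tests by distance bin, by treatment of the m1A libraries and without each library were chosen after the result below was seen.

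A signal appeared in the strand column of the m6A lists, which no comparison of the report used. For 594 reproducible m6A regions with a reproducible m1A region within 5 kb but not overlapping, the nearest one lay on the 3′ side by the m6A strand in 383, or 64.5% (95% exact binomial interval 60.5 to 68.3%). The exact binomial p was 1.6e-12, which treats neighbouring regions as independent. Without each library in turn the share was 62.5 to 68.2%. With m1A regions of 2 or more air libraries it was 63.8%, and with those of 2 or more ethylene libraries 57.4% (48.1 to 66.3%, 122 m6A regions), an interval that includes 50%, and the difference between treatments was not tested. By distance between midpoints, over all m1A regions, overlapping ones included, 239 lay within 500 bp on the 3′ side and 92 within 500 bp on the 5′ side. Midpoints at a distance of 0 have no side and were not counted apart, so these counts may overstate the difference between sides. Among regions that did not overlap, the nearest m1A region under 500 bp away lay on the 3′ side in 31 and on the 5′ side in 27.

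The tables argue against weak m6A peaks as the source, since the share was 68.1% with m6A peaks of score 100 or more, and against a bias along scaffold coordinates, since it was 62.3% on the plus strand and 66.4% on the minus strand. Peaks of neighbouring genes remain a candidate explanation, since the share was 63.8% for m1A regions 5 to 20 kb away, as high as within 5 kb. The same m6A regions may enter both windows, so the farther window is no independent check. Nor can either distance be assigned to the same gene or to a neighbouring one without an annotation. The share was also taken by distance bin, from the nearest m1A region within each bin that did not overlap. An m6A region can enter several bins, so the bins are not separate sets of regions. The share was 53.4% under 500 bp (58 m6A regions), 57.4% from 500 to 1000 bp, 66.2% from 1 to 2 kb, 64.2% from 2 to 3 kb and 70.9% from 3 to 5 kb. Farther out it was 66.9% from 5 to 10 kb, 60.2% from 10 to 20 kb, 54.1% from 20 to 50 kb, 49.5% from 50 to 100 kb and 49.4% from 100 to 200 kb. An inverted strand column cannot be told apart from a true 3′ side, because overlapping m6A peaks of different libraries had the same strand in 100% of cases, which shows only that the column is uniform. No annotation was used to place either mark in a transcript, and no biological explanation was tested.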

How the results depend on the processing

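Loci in place of regions, shared bp over the shorter list's bp, m6A peaks of score 100 or more and moves of 1.5 to 5 kb were chosen after the data were seen. Over 85 alternatives, 58 kept the direction and side of the threshold of the result, and 17 turned the direction. Alternatives for list lengths and m1A agreement used exact tests whose smallest possible p was 0.1 or more, so none of them could cross the threshold. Those for the m1A and m6A overlap all had the smallest possible placement permutation p of 0.002. The tally is therefore no measure of how robust the results are. The threshold was lost in 11, of which 2 also turned the direction, and gained in 4, of which 3 also turned it, and the cause was not tested except where stated. Thresholds here are unadjusted. The m1A list ratio stayed below 1 throughout (0.321 to 0.586 without each library), and the m6A list ratio was 0.907 to 1.07 without each library and 0.843 with peaks of score 100 or more. The m1A air-specific ratio, 0.997, moved around 1, at 1.07 (142 regions in place of 488) by the median score, 1.02 by 50% overlap, 1.71 (2 regions) with lists of equal length, 1.09 (permutation p = 0.0260) with loci, and 0.961 to 1.07 without each library, the highest without air library 3 (2960 regions against 2767, permutation p = 0.001). The m1A ethylene-specific ratio, 1.89, did not pass at 2.08 (7 regions in place of 13) by the median score, 1.75 by 50% overlap and 3.45 (4 regions) with lists of equal length. It was 1.10 to 1.895 without each library and passed only without air library 2 or air library 3, and with loci it was 2.91 (permutation p = 0.0060). The m6A air-specific ratio was 1.17 (79 regions in place of 138) by the median score and 0.943 to 1.39 without each library. The m6A ethylene-specific ratio was 1.22 (36 regions in place of 84) by the median score and 0.829 to 1.13 without each library, passing without air library 1 (0.829, permutation p = 0.0030) and in the other direction without ethylene library 2 (1.13, permutation p = 0.001). Without a library, a count of specific regions asks for fewer libraries and so changes by construction. Within minus between m1A agreement was -0.00876 as a share of the shorter list's peaks, -0.00668 as shared bp over the shorter list's bp and -0.0161 to 0.0471 without each library, on a scale of 0 to 1. The m1A and m6A overlap stayed above random placement at 1.58 to 2.64%.

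Replicate numbers recur across treatments, but presence deviations of same-numbered libraries correlated at -0.0123, 0.0498 and 0.0386 in m1A and 0.0265 in m6A, none over 0.1, so the numbers were not taken as pairs. Libraries of different number correlated at -0.100 to 0.0336 in m1A and -0.0265 in m6A, where 2 libraries per treatment force the opposite sign. The highest m1A values were of same-numbered libraries, so weak pairing was not excluded. With a replicate block, the geometric mean of the ratios of same-numbered libraries was 0.321 for m1A lists (exact permutation p = 0.5) and 0.983 for m6A lists. These equal the ratios of geometric means without pairing, so the move from 0.416 comes from the change of mean and not from the block. The specific ratios under the block were 0.971 and 1.54 for m1A air and ethylene and 1.31 and 0.893 for m6A air and ethylene. The m1A ethylene-specific count did not pass under the block (permutation p = 0.172), and no other call changed. Position in transcripts, the fixed gene groups and presence by gene were not run, since no annotation or gene names were used. Depth, unknown here, limits every count that rests on list length.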

Other observations

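Loci, the close pairs, the tests of list length and the splits of libraries were chosen after the data were seen.

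Peaks of all 10 libraries were chained into 17923 loci where gaps were 2 kb or less. Of loci with m1A, 8764 (51.7%) held 2 or more m1A regions, against 275 (9.29%) with 2 or more m6A regions among loci with m6A, but the m1A lists held 36717 regions against 3280, which alone gives more m1A regions per locus. Loci in a single library of the mark made up 39.8% of m1A loci and 48.1% of m6A loci, whereas by region the shares were 65.9% and 52.2%, over 6 and 4 libraries. The locus with most m1A regions was Peaxi162Scf00452 127952 to 143811, with 18 regions, peaks in all 6 m1A libraries and no m6A peak. The next, Peaxi162Scf00789 209526 to 227906, held 17 m1A regions and 1 m6A region, with peaks in 4 m1A and 4 m6A libraries. By locus, 231 were present in all 6 m1A libraries, against 60 by region, and 575 in all 4 m6A libraries, against 558. Both marks in 2 or more libraries each were held by 721 loci, 46.9% of the 1537 reproducible m6A loci and 7.06% of the 10215 reproducible m1A loci, and no chance share was computed for loci. Peaks of all 10 libraries met in 6 loci, Peaxi162Scf00015 299147 to 302983, Peaxi162Scf00096 1556854 to 1564862, Peaxi162Scf00126 1302683 to 1310599, Peaxi162Scf00338 184003 to 190954, Peaxi162Scf00378 666744 to 675238 and Peaxi162Scf00943 430614 to 435416, each with 1 m6A region and 5 to 7 m1A regions. These loci were chosen after their values were seen.

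An air-specific and an ethylene-specific m6A region lay within 2 kb of each other in 2 places. On Peaxi162Scf00344 the air region 1999270 to 1999386 and the ethylene region 1999056 to 1999162 were 107 bp apart, and on Peaxi162Scf00131 the regions named in the report were 1422 bp apart. Relabelling the 619 m6A regions found in exactly 2 libraries gave 0.801 such pairs on average over 10000 draws (one-sided permutation p = 0.187), so chance proximity was not excluded.

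The 6 m1A libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. Raw counts follow list length, so splits were compared by the ratio to the shuffles, the higher of both sides. In this separate set of shuffles the ethylene-specific ratio was 1.87 and the highest in another split 1.81, with 1 of the 10 splits, the real split, as high. The 1.81 was for air library 3 with ethylene libraries 2 and 3. Air library 3 with ethylene libraries 1 and 3 (1.47) or 1 and 2 (1.44) came next. Air library 3 and the ethylene libraries had the shortest m1A lists, so the high ratio cannot be tied to ethylene rather than to list length. The air-specific ratio was 0.997, against the same 1.81, with 7 of the 10 splits as high, the real split included.

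The m1A lists were shorter after ethylene on average, without passing the exact test. The authors' filter of numbered peaks is argued against as the source, since the highest peak number in each list, a lower bound on the number before that filter, had on average the same ratio of ethylene to air, 0.416. A difference in library depth may contribute and stays open, since no file gives depth. Over the 6 libraries, list length and the share of peaks at a score of 3100 or more, the only correlation across libraries that was computed, had a Spearman rho of -0.714 (exact permutation p = 0.136) and a Pearson r of -0.621 (exact permutation p = 0.185), and r was -0.663 without the 2 libraries farthest from the median length. An effect of ethylene on m1A also stays open, as untested apart from depth.

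The m6A-titled lists resembled each other more than the m1A lists did, although the protocol text gives 1 antibody for both. Different score floors are argued against, since with m6A peaks of score 100 or more the lowest Jaccard index among m6A lists was 37.2%, above the highest among m1A lists, 20.9%. Unequal lengths lower the index in many m1A pairs, but hardly in the pair at 20.9%, whose lists covered 3041 and 3435 kb. Use of 1 antibody in both sets cannot be told apart from use of different ones. At most 34.2% of m6A-titled peaks of score 100 or more (28.0 to 34.2% over libraries) overlapped the longest m1A list, below the 35.8 to 40.8% of the other m1A lists, which met the bound set in advance against 1 antibody. These m6A-titled peaks were wider, with mean widths of 367 to 408 bp against 149 to 199 bp in the other m1A lists. Greater width favours overlap, and the shares were not adjusted for it. That bound was set aside after the result was seen, because the gap for the longest list is smaller than the spread between lists. The sets were also processed differently, with 40.9 to 45.4% of numbered peaks kept in m6A lists and 65.1 to 73.4% in m1A lists. The gap was wider for other m1A lists, with m6A-titled peaks of any score. Air library 1 was overlapped by 21.2 to 23.4% of m6A-titled peaks and 35.1 to 36.3% of peaks of the shorter m1A lists. For ethylene library 3 the shares were 10.5 to 11.8% and 23.4 to 27.8%. These shares go against 1 antibody only if both sets were processed alike, which they were not.

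Overlapping peaks of different libraries often shared an exact edge. Within m6A pairs the start was identical for 85.3 to 88.9% of overlapping peaks, within m1A pairs for 34.4 to 48.0%, and between an m6A and an m1A list for 38.1 to 54.6%. The end was identical for 84.5 to 88.6%, 35.1 to 47.2% and 34.2 to 56.9%.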
